A study of Mus musculus with 6 samples.

How the data were processed

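RNA from mouse skin was measured on 6 single-colour Affymetrix arrays of biotin-labelled total RNA. The mice were C57BL/6 and carried a subcutaneous pump that released its content for 7 days. The labels put 1 array in each of 4 groups, namely PBS at the pump outlet (PBS local), PBS far from it on the abdomen (PBS distal), IL-13 at the outlet and TSLP at the outlet. The TGF-beta group has 2 arrays, which the labels give to mouse 1 and mouse 2. The labels do not say whether the PBS local and PBS distal pieces came from the same mouse.

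The deposited values are linear intensities, 1 per probe set and array, and were made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The trimmed mean of each array, leaving out 2% at each end, lay between 500.16 and 500.2 in the deposited intensities, so the arrays had already been brought to a common scale. Detection calls were not used here, and 0 per-sample columns were left unused. The table holds 22690 probe sets, of which 64 are AFFX controls. Of the others, 20380 name 1 gene in the platform annotation, 691 name several, and 1555 are unnamed here. Symbols of 20351 probe sets were matched by gene number to a RefSeq table of the assembly GRCm38.p6, which was used for names only. No genome build is given in the sources used here, and no coordinates are printed.

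Each array was scaled to the mean of the 6 trimmed means, which moved values very little. Values were then taken as log2(signal + 27.4), where the offset is the 25th percentile of all scaled values. Differences are on that scale, which understates the change of dim genes. Of several probe sets naming 1 gene, the one with the highest mean log2 value stood for it, which gave 12393 genes, of which 4956 had more than 1 probe set. Of the kept probe sets, 1251 end in s_at or x_at and can bind related transcripts. The named genes past the size rule had 66 other probe sets, of which 31 passed the filter on dim genes and 0 of these 31 had the opposite sign. A gene entered a comparison if at least 1 compared array had it at or above 165, the median of all scaled values.

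TGF-beta was compared with PBS local in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with an intensity trend. All 6 arrays were fitted in 5 groups, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The spread came from the 2 TGF-beta mice alone, with 1 residual degree of freedom and 3.13 prior degrees of freedom, and the single PBS local array was assumed to vary like them. TGF-beta was set against IL-13 and against TSLP in the same fit. Beside the test stood a size rule, a difference of at least 1 on the log2 scale (2-fold), which for TGF-beta had to hold in the same direction in both mice. IL-13, TSLP and PBS distal had 1 array each, so their differences from PBS local have no replicate check. As an alternative they were tested in the same limma fit with the spread of the TGF-beta mice borrowed. Their counts were set beside the number of genes that differed as much between the TGF-beta mice. The number of arrays limits the precision of every value.

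The limma step was tested on simulated data for TGF-beta against PBS local, with noise resampled from the mouse pair. Of 50 genes at each size, it recovered 8% at 2-fold, 76% at 4-fold, 96% at 8-fold and 92% at 16-fold, and it called 33 of 7541 unchanged genes. With noise drawn from a model the shares were 6%, 90%, 98% and 98%, with 9 unchanged genes called. The simulated data held 200 changed genes, and the Benjamini-Hochberg adjustment depends on how many genes change. The real comparison had 0 genes at least 4-fold higher or lower in both mice, so these shares do not carry over to it. With resampled noise the correct calls numbered 4, 38, 48 and 46. The 33 false ones were a larger share of all calls than the threshold allows.

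Gene lists for cell types and pathways were fixed before the data were examined. A list with at least 5 measured members was described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. This describes these arrays and is not a test, and a list is called outside the band when its percentile lies below 2.5 or above 97.5. Of 100 random lists of 15 unchanged genes, 4 fell outside that band. For TGF-beta the members past limma's threshold were also counted, adjusted over the list alone. The eosinophil list and the mammary and simple epithelium list had 0 measured members in every comparison, and neither has a value here.

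The cytokine comparisons share 1 control array. Their overlaps and correlations were therefore set beside 200 simulations of unchanged arrays with noise from the TGF-beta mouse pair (larger than the IL-13 and TSLP differences themselves), beside the overlap of independent lists, and beside correlations in which one cytokine was set against PBS distal.

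The named genes were chosen by a rule fixed before the data were examined. For each comparison with PBS local they are the 12 largest positive and 8 largest negative differences past the size rule, for TGF-beta ranked by the smaller of the mice's differences, with genes past limma's threshold first had there been any. They also include the 5 largest in each direction between cytokines, up to 10 per direction shared by all 3 cytokines, and up to 4 members of each list with the largest absolute difference. A further set was named whatever its values, and those analysed here are Col1a1, Col3a1, Ccn2, Postn, Comp, Acta2, Tgfbi, Timp1, Arg1, Chil3, Retnla, Ccl11, Ccl17, Ccl24, Il13ra2, Cish, Tgfb1, Il13, Tslp, Tgfbr1, Tgfbr2, Il13ra1, Il4ra, Crlf2 and Il7r. Probe sets with no or several symbols and symbols that are only clone names, predicted gene numbers or sequence tags were passed over.

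Alternatives covered the scaling, the offset, the filter on dim genes, the probe set standing for a gene, the control array, the size rule, limma's settings and leaving out each TGF-beta mouse. In 1 alternative, chosen after the data had been seen, genes at least 2-fold apart between the TGF-beta mice were left out.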

Results

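Mouse skin was profiled after 7 days of continuous subcutaneous release of PBS, IL-13, TSLP or TGF-beta, and the series asks what each cytokine does to the skin around the pump. IL-13 is a cytokine of type 2 immunity, TSLP is an epithelial cytokine that acts on dendritic cells and lymphocytes, and TGF-beta is a regulator of matrix production. There were 2 arrays for TGF-beta, from separate mice, and 1 array each for IL-13, TSLP, PBS at the pump outlet and PBS in distal abdominal skin. Array medians ran from 160 to 171 signal units, and the 3'/5' signal ratio of Actb from 1.13 to 1.25. Values are differences in log2(signal + 27.4), and where a group has 1 array no error can be given.

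Under TGF-beta, a small set of genes was higher in both mice than in PBS skin at the outlet. Cxcl5, a neutrophil chemokine, was higher by 3.49 in mouse 1 and 1.93 in mouse 2. The matrix protease Mmp3 was higher by 1.99 and 1.88, and Sfrp2, a secreted Wnt regulator, by 2.47 and 1.43. Bambi, a pseudoreceptor of the TGF-beta family, was higher by 1.07 and 2.41, and Ccn4 by 1.64 and 1.14. Lyve1, a marker of lymphatic vessels, was lower by a mean of -1.33, and the hyaluronan synthase Has2 by -1.30.

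The other genes highest in both mice were Sox4 (mean 1.60), Tcfl5 (1.37), Colec12 (1.33), Gzma (1.25), Clec4d (1.24), Cxcl2 (1.21) and Saa3 (1.10). The lowest were Spon2 (-1.79), the paraoxonase Pon1 (-1.59), Crp (-1.40), Neu2 (-1.35), Hemgn (-1.26) and Slc27a3 (-1.19). Of 7741 genes, 14 were at least 2-fold higher and 12 at least 2-fold lower in both mice. No gene passed limma's threshold, with a smallest adjusted p of 0.864 and 355 genes at an unadjusted p under 0.05. Of the 7741, mouse 1 alone had 27 higher and 47 lower, and mouse 2 alone had 143 and 112. Independent lists would share 0.499 higher and 0.68 lower genes, and 11 genes went in opposite directions. Both mice were set against the same PBS local array. Error in that array can put genes in both lists, so the numbers for independent lists are no chance expectation. Pearson's r between the mice's differences, across genes that are not independent replicates and against 1 shared control, was 0.379. Simulated unchanged single arrays against that control, standing for IL-13 and TSLP, had a mean r of 0.498. That value follows from the shared control and the equal noise given to all simulated arrays. The mice's differences had unequal SDs across genes, 0.303 in mouse 1 and 0.541 in mouse 2, so it is no benchmark for 0.379.

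The matrix genes that TGF-beta is known for differed little from PBS skin at the outlet. They were higher than in PBS distal skin, as they were under the other cytokines, PBS skin at the outlet being itself above distal skin. Against distal skin the collagen median was 0.94 under TGF-beta, 0.92 under IL-13 and 0.52 under TSLP, that of the matrix glycoproteins and proteoglycans 1.15, 1.16 and 0.75, of the matrix proteases and inhibitors 0.95, 1.37 and 1.13, and of the TGF-beta response genes 0.52, 0.39 and 0.24. The values that follow are against PBS local. The 14 fibrillar and network collagens had a median of 0.16 (mouse 1 0.33, mouse 2 0.03), and 0 of them were 2-fold higher or lower in both mice, Col11a1 having the largest mean difference, with 0.81 in mouse 1 and 2.81 in mouse 2. Col1a1 was at 0.17, Col3a1 at 0.21, Postn at 0.31 and Acta2, the myofibroblast actin, at 0.35. Ccn2 was at 0.83 in mouse 1 and -0.04 in mouse 2, Tgfbi at a mean of -0.07, Comp, below the filter on every array, at -0.35 and Timp1, a protease inhibitor, at 0.80. The 25 TGF-beta response genes had a median of 0.18 over the genes' means of both mice (mouse 1 alone 0.13, mouse 2 alone 0.12). It lay at the 99.8th percentile of random lists, and 2 of the genes (Bambi and Ccn4) were 2-fold higher in both mice. The 21 matrix glycoproteins and proteoglycans lay at 0.18 (mouse 1 0.38, mouse 2 0.04), and the 16 matrix proteases and inhibitors at 0.23 (0.34 and 0.10), with 1 of 16 (Mmp3) 2-fold higher. The receptors Tgfbr1 and Tgfbr2 were at 0.27 and -0.24, and Tgfb1, below the filter on every array, at -0.11 in mouse 1 and 0.11 in mouse 2.

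Of the other lists, the 8 stressed keratinocyte genes had a median of 0.58, with Krt6b at 1.00 and S100a8 at 0.92. Lists below the band included antigen presentation (median -0.22), basal keratinocyte (-0.22), monocyte chemokines and acute inflammation (-0.23, although Cxcl5 is a member; -0.35 in mouse 1 and -0.08 in mouse 2), type 2 immunity (-0.27), mast cell (-0.30) and B and plasma cell genes (-0.50, but -0.05 in mouse 1 and -0.83 in mouse 2). Arg1 was at 1.93 in mouse 1 and 0.60 in mouse 2, while Chil3 was at a mean of -1.34, Selp at -1.07, Retnla at -1.02, Il4ra at -0.71 and Cish at -0.60. Against PBS distal, Hemgn and Selp and the mast cell, B cell and chemokine lists were higher under TGF-beta, not lower, and the antigen presentation (-0.12), type 2 immunity (-0.07) and ribosomal protein (0.08) lists lay inside the band. Against PBS local, the endothelial and lymphatic list, with Lyve1 its lowest member, lay above the band at 0.10, with 0.36 in mouse 1 and -0.18 in mouse 2. Skeletal muscle genes lay at -0.25, but at 0.04 in mouse 1 and -0.51 in mouse 2. In all, 8 of 33 lists lay above the band and 7 below. The reference list of 10 ribosomal proteins was itself at 0.29 and the 99th percentile, so a percentile outside the band does not mark a list as special. Adjusted over the list alone, limma called 3 neutrophil genes, 2 chemokine and acute inflammation genes, 2 stressed keratinocyte genes, 2 endothelial and lymphatic genes, and 1 gene each in the protease, IL-4 and IL-13 response, and T and NK cell lists, against 0 over all genes. These counts were not corrected across the 33 lists and give no direction. Ngp, the neutrophil gene with the largest mean difference, was at -1.24. Hair follicle genes set the mice apart. Krt25, an inner root sheath keratin, was higher by 0.53 in mouse 1 and 8.37 in mouse 2, and the 23 list members had medians of 0.10 and 4.81. Of the 133 genes at least 2-fold higher in mouse 2 than in mouse 1, 40 were keratin, keratin-associated or hair list genes.

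**Figure D1:**
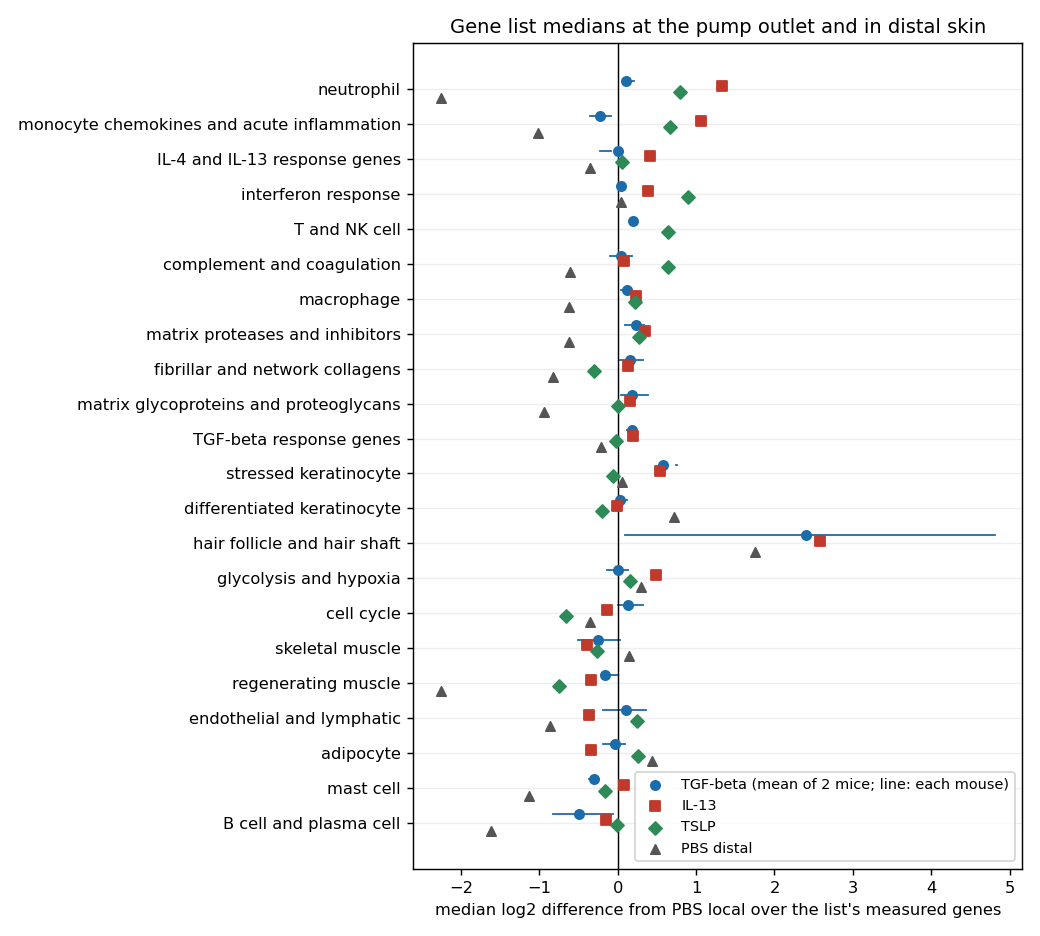
Median log2 difference from PBS local for 22 of the gene lists, each with at least 5 measured members in the comparison shown; symbols stand for the comparison and the blue lines join the medians of the TGF-beta mice. Neutrophil genes lay at 1.33 under IL-13, 0.80 under TSLP and -2.25 in PBS distal skin, and the hair follicle line runs from 0.10 to 4.81.

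On the 1 array of skin under IL-13, several neutrophil chemokines, matrix proteases and IL-13 response genes had higher transcripts than in PBS skin at the outlet. Cxcl5 was higher by 4.33, Cxcl2 by 3.05 and Cxcl1 by 2.72, all ligands of a neutrophil receptor. The collagenase Mmp13 was higher by 4.06 and the macrophage elastase Mmp12 by 3.90. Arg1, the arginase of alternatively activated macrophages, was higher by 3.37, the decoy receptor Il13ra2 by 2.06, the eosinophil chemokine Ccl24 by 1.94 and the chitinase-like Chil3 by 1.87. Car4, a carbonic anhydrase, was higher by 4.11.

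Of the 20 measured IL-4 and IL-13 response genes, 5 were at least 2-fold higher, with a median of 0.41. The neutrophil list had 6 of 10 at least 2-fold higher (median 1.33), the list of monocyte chemokines and acute inflammation 8 of 16 (1.06), and the matrix proteases 6 of 19 (0.35). Glycolysis and hypoxia genes had 3 of 15 (0.49), among them the glucose transporter Slc2a1 at 1.28 and Adm at 1.07. Collagen crosslinking genes lay at 0.30 with Lox at 0.90, while the collagens themselves lay at 0.14 with Col1a1 at 0.15 and Col3a1 at 0.16. Timp1 was at 1.26, Ccl11 at 0.95, Ccl17, below the filter on every array, at 0.75, Retnla at 0.62 and Il13ra1 at 0.42. Il13 itself had a signal of 8.94 under IL-13 and 3.36 in PBS skin, far below the filter, and Tslp one of 105 against 146. Interferon response genes lay at 0.38 with 2 of 19 at least 2-fold higher, Cxcl10 at 1.32 and Ifit2 at 1.14, and macrophage genes at 0.24. The 6 lists below the band were skeletal muscle (-0.39), endothelial and lymphatic (-0.37), regenerating muscle (-0.34), adipocyte (-0.34), basal keratinocyte (-0.30) and oxidative phosphorylation (-0.07), against 12 above, of 32. The lowest genes were Smtnl1 (-2.32), Igha (-1.85), Pon1 (-1.68), Apobec2 (-1.34) and Pdk4 (-1.33). The hair follicle list stood at 2.58 over 8 members, all but Dct of which were below the filter in PBS skin, and at 1.32 over the 23 members that passed it on any array, with Krt25 at 4.76, Krtap8-1 at 3.67, Krt27 at 3.41 and Tchh at 2.90, and with Krtap15 at 3.19 outside it.

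In all, 85 genes were at least 2-fold higher and 31 at least 2-fold lower under IL-13, of 7562. The 2 TGF-beta mice differed from each other as much in 186 of 7597 genes, and without the genes that did so, the counts under IL-13 were 47 and 18. Of the 85, 16 belong to a set of exocrine pancreas genes (Prss2, Clps, Cel and others) and 9 are keratin, keratin-associated or hair list genes; both sets were picked out after their values were seen. With the spread of the TGF-beta mice borrowed, limma called 0 genes, with a smallest adjusted p of 0.432 and 292 genes at an unadjusted p under 0.05. Over all settings its smallest adjusted p ran from 0.00934 to 0.954, and after quantile normalization it called 3 genes (Car4, Cxcl1 and Cxcl2), all higher. Against PBS distal it called 9, all higher, and Igha and the endothelial and lymphatic and regenerating muscle lists were higher under IL-13, and the stressed keratinocyte list (0.54 against PBS local) was lower. The glycolysis and hypoxia list then lay at 0.09, inside the band, the interferon response list at 0.16 and the 8 hair follicle genes at 0.45. Differences from PBS distal mix the cytokine with the pump and the body site. Ankrd1 and Saa3, among the 9 called, were also lower in PBS distal than in PBS local skin.

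The 1 array of skin under TSLP had higher transcripts of several neutrophil chemokines, as under IL-13, and of interferon response genes. Cxcl9, an interferon-induced T cell chemokine, was higher by 3.45, and the guanylate-binding protein gene Gbp8 by 2.23, with Iigp1 at 1.77 and Gbp2 at 1.72. Cxcl5 was higher by 4.15, Cxcl2 by 2.80, Cxcl1 by 2.78, Il6 by 2.29, Mmp12 by 2.79 and Acod1, an enzyme of activated macrophages, by 2.14. Ankrd1, a stress gene of striated muscle, was lower by -3.25.

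Of 20 interferon response genes, 9 were at least 2-fold higher and all 20 had a positive difference (median 0.90, against 0.38 under IL-13, a difference that was not tested). Of the 6 measured T and NK cell genes, 2 were at least 2-fold higher (Gzma at 1.41 and Gzmb at 1.38; median 0.64). Complement genes lay at 0.64, neutrophil genes at 0.80 with 2 of 10 at least 2-fold higher, monocyte chemokines and acute inflammation at 0.67 with 4 of 13, matrix proteases at 0.28 with 3 of 16, and antigen presentation at 0.23. Of 19 IL-4 and IL-13 response genes, 3 were at least 2-fold higher, namely Arg1 (1.66), Clec7a and Retnla (both 1.13), and the list median was 0.06. Ccl17, below the filter on every array, was at 1.37, Chil3 at -0.39 and Ccl24 at 0.38. The 9 type 2 immunity genes lay at 0.24, with Il33 at 0.56, Il7r at 0.44 and the TSLP receptor gene Crlf2 at 0.24. The 8 regenerating muscle genes had a median of -0.74 (Chrna1 -1.76, Myl4 -1.58), the 20 cell cycle genes -0.65 (Cdc20 -1.05), and the collagens -0.30 (Col15a1 -1.05, Col8a1 -1.02, Col1a1 -0.39). Adipocyte genes and endothelial and lymphatic genes both lay at 0.25, and skeletal muscle genes at -0.26. Of 32 lists, 12 lay above the band and 7 below. Other extremes were Ubd (2.09), Klk1 (1.96, in the exocrine pancreas set), Sfrp2 (1.94), Zdhhc12 (1.91), Greb1 (-2.68), Tnfrsf12a (-2.02), Ngfr (-1.90), Xirp1 (-1.88) and Alpk2 (-1.65).

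In all, 76 genes were at least 2-fold higher and 34 lower under TSLP, of 7614, again fewer than the 186 between the TGF-beta mice, and 52 and 29 without the genes that set those mice apart. Of the 76, 16 belong to the exocrine pancreas set. With the borrowed spread limma called 0 genes, with a smallest adjusted p of 0.544 and 304 genes at an unadjusted p under 0.05. Over all settings its smallest adjusted p ran from 0.00200 to 1.00, and after quantile normalization it called 6 higher (Cxcl1, Cxcl2, Cxcl9, Gbp2, Iigp1 and Mmp3) and 1 lower (Ankrd1). Against PBS distal it called 3, all higher (Clec4d, Prg4 and Saa3), and Ankrd1, Xirp1, Alpk2, Myl4, Col8a1 and the collagen and regenerating muscle lists were higher under TSLP, and Retnla and the adipocyte list were lower. The cell cycle list then lay at -0.18 over 16 members, and it and the adipocyte and antigen presentation lists lay inside the band. Differences from PBS distal mix TSLP with the pump and the body site. Clec4d, Prg4 and Saa3 were also lower in PBS distal than in PBS local skin, where no cytokine was given.

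**Figure D2:**
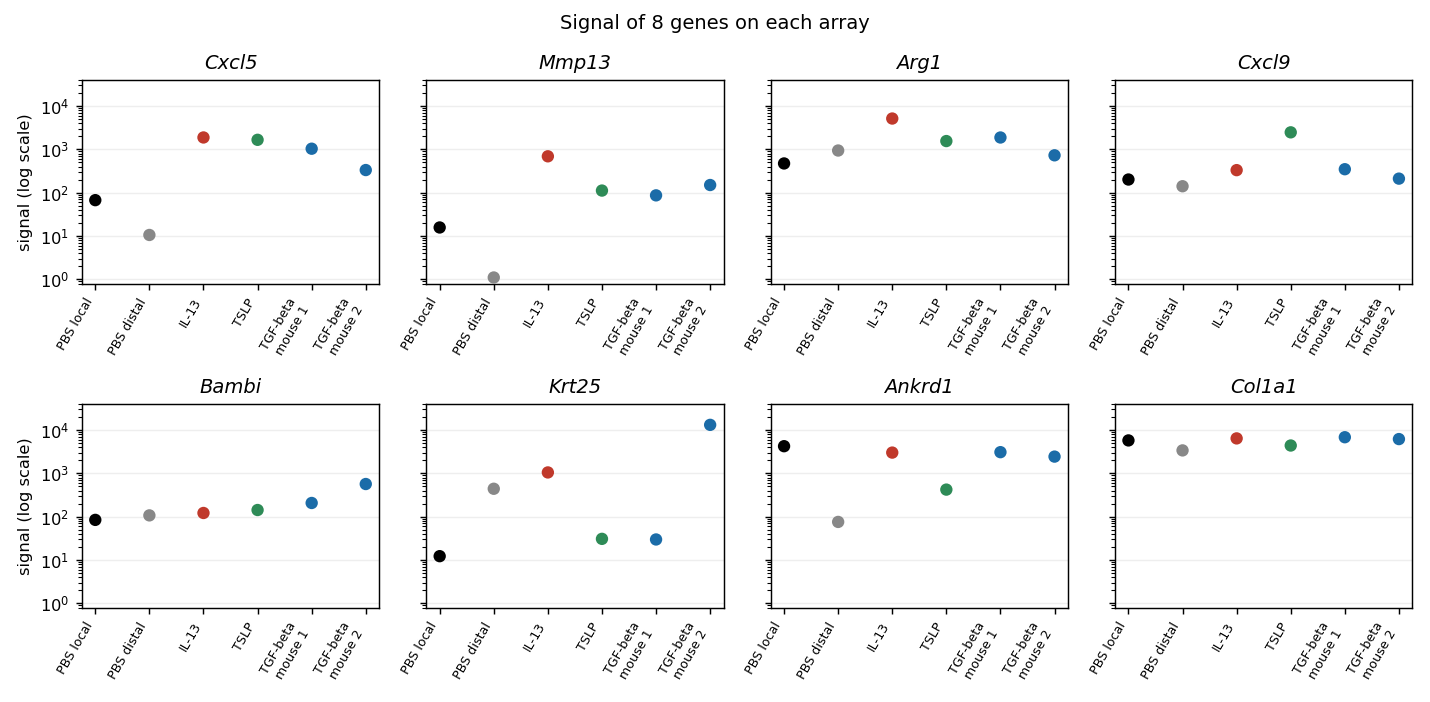
Signal on each of the 6 arrays, on a log axis, for 8 genes; each point is 1 array, and the TGF-beta mice have a point each. Cxcl9 stands at 2473 under TSLP, against 202 in PBS local, and Krt25 at 13132 in TGF-beta mouse 2, against 29.8 in mouse 1.

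Distal skin under PBS differed from skin at the outlet more than any cytokine array did by the size rule. Among the genes lowest in distal skin were Ankrd1 at -5.37, the embryonic and perinatal myosins Myh3 at -4.60 and Myh8 at -3.81, the acute phase gene Saa3 at -4.39 and the lubricin gene Prg4 at -4.15. Of the adult myosins, Myh4 was higher by 2.78 but Myh2 was at -1.78 and Myh1 at -0.36, and the skeletal muscle list lay at 0.14. Higher were also the hair follicle genes Krt25, Krt27 and Tchh by 3.56, 2.94 and 2.53. Retnla was higher by 3.18.

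All 9 measured neutrophil genes were at least 2-fold lower in distal skin (median -2.25, S100a9 -2.99), as were 7 of 8 regenerating muscle genes (-2.25) and 5 of 5 B and plasma cell genes (-1.62). Mast cell genes lay at -1.13 (4 of 7 at least 2-fold lower), monocyte chemokines and acute inflammation at -1.02, matrix glycoproteins and proteoglycans at -0.94 (10 of 21, with Tnc at -3.31 and Thbs4 at -3.64), endothelial and lymphatic genes at -0.87, collagens at -0.82 (Col1a1 -0.76, Col8a1 -3.59), and macrophage genes at -0.62. Differentiated keratinocyte genes were at 0.71, with Flg, the barrier protein filaggrin, at 1.54, adipocyte genes at 0.43, and basal keratinocyte and sebaceous gland genes both at 0.34. Timp1 was at -2.41 and Il4ra at -1.06. Of 32 lists, 7 lay above the band and 17 below. In all, 60 genes were at least 2-fold higher and 267 lower, of 7617. Other extremes were Tnni1 (-4.08), Ankrd2 (-4.02), Inmt (2.39), Ddit4l (2.22) and Aqp4 (2.06). With the borrowed spread limma called 2 genes (Ankrd1 and Saa3, lowest adjusted p 0.0469), with 831 at an unadjusted p under 0.05, and after quantile normalization 11 higher and 109 lower. Its smallest adjusted p ran from 2.54e-05 to 0.235 over all settings, with 0 genes called at the higher offset, with a floor, without the filter on dim genes or with the mean of all probe sets. It called 1 lower (Saa3) with every compared array above the filter, 3 lower at the lower offset, and 1 higher and 27 lower without the genes apart between the TGF-beta mice.

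Set against each other, the cytokines parted on a few genes. Car4, Chil3, Cxcl1, Mmp12 and Mmp13 were lower under TGF-beta than under IL-13, with Chil3 at a mean of -3.21 and Car4 at -3.14, and Mest (1.56) and Actc1 (1.30) were the 2 genes at least 2-fold higher in both mice. Against TSLP, Cxcl9 (-3.06), Cxcl1 (-2.53), Retnla (-2.15), Il6 (-1.97) and Gbp2 (-1.84) were lower under TGF-beta, while Ankrd1 (2.62), Myl4 (2.03), Tnni1 (1.79), Tnnc1 (1.63) and Krt6b (1.46) were higher. IL-13 exceeded TSLP in Krt25, Krtap8-1, Krt27, Krtap15 and Ankrd1 (2.76), and was below it in Cxcl9 (-2.80), Zdhhc12 (-2.69), Thrsp (-2.44), Smtnl1 (-2.30) and Gbp8 (-2.20). The keratin and keratin-associated genes among these also set the TGF-beta mice apart. Krt25 had signals of 29.8 in mouse 1 and 13132 in mouse 2, and Krtap15 of 5.97 and 723. With 1 array each, IL-13 and TSLP cannot be told apart from their mice. By the size rule, 2 genes were higher and 33 lower in TGF-beta against IL-13, 13 and 40 against TSLP, and 42 and 62 in IL-13 against TSLP. limma called 0 genes in either TGF-beta comparison, with smallest adjusted p of 0.692 and 0.643, and 179 and 568 genes at an unadjusted p under 0.05. After quantile normalization it called 4 genes in each.

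Shared by all 3 cytokines were 6 genes at least 2-fold higher, Cxcl5, Sfrp2, Mmp13, Mmp3, Clec4d and Cxcl2, and 1 lower, Crp. Here a gene counted if any array of the 3 comparisons passed the filter, which leaves 7857 genes. Mmp13 passed it under IL-13 only and is not among the 14 genes of the TGF-beta comparison. Independent lists would share 0.00203 higher genes. Unchanged arrays set against the 1 PBS local array, with noise as large as between the TGF-beta mice, gave a mean of 38.3 higher and 37.4 lower, above the counts seen. That noise had an SD of 0.512 across genes, against 0.362 for the whole IL-13 difference and 0.321 for that of TSLP, so it is too large for an overlap to exceed and sets no useful bound. IL-13 and TSLP shared 40 higher and 3 lower genes, against simulated means of 49.4 and 48.6. Of the 40, 16 belong to the exocrine pancreas set and 17 were less than 2-fold apart between the TGF-beta mice. Pearson's r across genes was 0.695 for TGF-beta and IL-13 (simulated 95% range 0.515 to 0.627). It was 0.491 for IL-13 and TSLP (0.440 to 0.564) and 0.35 for TGF-beta and TSLP (0.519 to 0.630). The covariances of these pairs, 0.0924, 0.0588 and 0.0400, all lay below their simulated ranges, whose lower ends were 0.108. With noise of that size, the ranges of the covariances set no useful bound. The ranges of r follow from the shared control and the equal noise given to all simulated arrays, so they set no useful bound either. For TGF-beta and IL-13, r was 0.538 with mouse 1 alone and 0.618 with mouse 2 alone. With one cytokine set against PBS distal instead, r was 0.257 or 0.411 for TGF-beta and IL-13, 0.237 for IL-13 and TSLP, and 0.019 or 0.159 for TGF-beta and TSLP. Genes are not independent replicates, and how much of each overlap comes from the shared control was not settled.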

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

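The alternative without genes at least 2-fold apart between the TGF-beta mice was chosen after the data were seen; all others were set beforehand. No paired analysis was possible because the labels number the mice of the TGF-beta group only. Of the counts and correlations, 298 values under alternatives stayed within 1.5 times the main count or within the spread, and 169 did not. Of the list medians 1085 stayed, 280 moved and 20 reversed, and of the named genes 6009, 1076 and 12. Without scaling, 0 results moved. The cause was not tested except where the alternative itself sets it, as with a stricter or looser rule or filter. With 1 TGF-beta mouse left out, limma had no residual degrees of freedom, and those settings have the size rule only. Values near background limit the counts, and a lone array has no replicate check.

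With PBS distal as the control, the numbers of genes were 200 higher and 95 lower for TGF-beta, 352 higher and 217 lower for IL-13, and 385 higher and 107 lower for TSLP. limma called 4 higher for TGF-beta and, with the spread borrowed, 9 for IL-13 and 3 for TSLP. Genes shared by cytokines numbered 182 higher and 82 lower for TGF-beta and IL-13, 177 higher and 47 lower for TGF-beta and TSLP, 273 higher and 72 lower for IL-13 and TSLP, and 165 higher and 42 lower for all 3 cytokines. Pearson's r across genes was 0.885 for TGF-beta and IL-13, 0.765 for TGF-beta and TSLP, and 0.824 for IL-13 and TSLP. Every cytokine array came from the outlet, so all values against PBS distal mix the cytokine with the pump and the body site. The counts, calls, overlaps and r here cannot be read as effects of a cytokine. The numbers of lists were 19 above the band for TGF-beta and 19 above the band for TSLP. The list medians were 0.99 for mast cell under TGF-beta, 1.29 for B cell and plasma cell under TGF-beta, 0.96 for monocyte chemokines and acute inflammation under TGF-beta, -0.57 for stressed keratinocyte under IL-13, 2.14 for regenerating muscle under IL-13, 0.50 for endothelial and lymphatic under IL-13, 0.52 for fibrillar and network collagens under TSLP, -0.19 for adipocyte under TSLP, and 1.28 for regenerating muscle under TSLP. Further values were -0.015 for glycolysis and hypoxia under TSLP. The log2 differences were 1.63 for Hemgn under TGF-beta, 0.28 for Selp under TGF-beta, 0.72 for Igha under IL-13, 2.12 for Ankrd1 under TSLP, 1.30 for Xirp1 under TSLP, 0.44 for Alpk2 under TSLP, 1.28 for Myl4 under TSLP, -2.05 for Retnla under TSLP and 2.57 for Col8a1 under TSLP.

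With the mean of both PBS arrays as the control, the numbers of genes were 55 higher and 19 lower for TGF-beta, 156 higher and 59 lower for IL-13, and 163 higher for TSLP. The shared genes numbered 42 higher and 9 lower for TGF-beta and IL-13, 30 higher for TGF-beta and TSLP, 96 higher and 5 lower for IL-13 and TSLP, and 27 higher and 2 lower for all 3 cytokines. Pearson's r across genes was 0.771 for TGF-beta and IL-13, 0.513 for TGF-beta and TSLP, and 0.645 for IL-13 and TSLP. The numbers of lists were 17 above the band for TGF-beta. The list medians were 0.46 for mast cell under TGF-beta, 0.41 for B cell and plasma cell under TGF-beta, 0.34 for monocyte chemokines and acute inflammation under TGF-beta, -0.40 for stressed keratinocyte under IL-13, 0.92 for regenerating muscle under IL-13, 0.064 for endothelial and lymphatic under IL-13, and 0.066 for fibrillar and network collagens under TSLP. The log2 differences were 0.18 for Hemgn under TGF-beta, -0.46 for Retnla under TSLP and 0.77 for Col8a1 under TSLP.

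At a 4-fold size rule, the numbers of genes were 0 higher and 0 lower for TGF-beta, 21 higher and 1 lower for IL-13, 10 higher and 3 lower for TSLP, and 8 higher and 66 lower for PBS distal. Cytokine against cytokine, they were 0 higher and 5 lower in TGF-beta against IL-13, 1 higher and 2 lower in TGF-beta against TSLP, and 12 higher and 7 lower in IL-13 against TSLP. Genes shared by cytokines numbered 0 higher and 0 lower for TGF-beta and IL-13, 0 higher and 0 lower for TGF-beta and TSLP, 5 higher and 0 lower for IL-13 and TSLP, and 0 higher and 0 lower for all 3 cytokines.

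At a 1.5-fold rule, the shared genes numbered 50 higher and 51 lower for TGF-beta and IL-13, 32 higher and 35 lower for TGF-beta and TSLP, 104 higher and 51 lower for IL-13 and TSLP, and 28 higher and 24 lower for all 3 cytokines.

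With the offset at the 50th percentile, the numbers of genes were 5 higher and 2 lower for TGF-beta, 50 higher and 10 lower for IL-13, 42 higher and 18 lower for TSLP, and 24 higher and 144 lower for PBS distal. Cytokine against cytokine, they were 0 higher and 16 lower in TGF-beta against IL-13, 5 higher and 19 lower in TGF-beta against TSLP, and 20 higher and 25 lower in IL-13 against TSLP. Genes shared by cytokines numbered 3 higher and 0 lower for TGF-beta and IL-13, 3 higher and 1 lower for TGF-beta and TSLP, 22 higher and 1 lower for IL-13 and TSLP, and 3 higher and 0 lower for all 3 cytokines.

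With the offset at the 10th percentile, the numbers of genes were 29 higher for TGF-beta and 48 lower for IL-13. Between the cytokines the numbers were 4 higher in TGF-beta against IL-13 and 22 higher in TGF-beta against TSLP. The shared genes numbered 22 higher and 4 lower for TGF-beta and IL-13, 14 higher for TGF-beta and TSLP, and 12 higher for all 3 cytokines.

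With a floor at the 40th percentile and no offset, the numbers of genes were 49 lower for IL-13. Cytokine against cytokine, they were 4 higher in TGF-beta against IL-13. Genes shared by cytokines numbered 4 lower for TGF-beta and IL-13, and 5 lower for TGF-beta and TSLP. Pearson's r across genes was 0.634 for TGF-beta and IL-13.

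With every compared array at or above the median, the numbers of genes were 8 higher and 6 lower for TGF-beta, 44 higher for IL-13, 48 higher for TSLP, and 38 higher and 137 lower for PBS distal. Between the cytokines the numbers were 18 lower in TGF-beta against IL-13, 7 higher and 24 lower in TGF-beta against TSLP, and 20 higher in IL-13 against TSLP. The shared genes numbered 3 higher and 0 lower for TGF-beta and IL-13, 4 higher and 1 lower for TGF-beta and TSLP, 16 higher for IL-13 and TSLP, and 3 higher and 0 lower for all 3 cytokines.

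With no filter on dim genes, the numbers of genes were 131 higher for IL-13 and 101 higher for PBS distal. Cytokine against cytokine, they were 7 higher in TGF-beta against IL-13 and 81 higher in IL-13 against TSLP.

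With the mean of all probe sets of a gene, between the cytokines the numbers were 8 higher in TGF-beta against TSLP.

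After quantile normalization, limma called 4 in TGF-beta against IL-13 and 4 in TGF-beta against TSLP. Genes shared by cytokines numbered 1 lower for TGF-beta and IL-13, and 0 lower for all 3 cytokines.

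In limma with the spread of the TGF-beta mice borrowed, the numbers of genes were 0 higher and 0 lower for IL-13, 0 higher and 0 lower for TSLP, and 0 higher and 2 lower for PBS distal.

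Without genes at least 2-fold apart between the TGF-beta mice, the numbers of genes were 47 higher and 18 lower for IL-13. Cytokine against cytokine, they were 27 higher in IL-13 against TSLP. Genes shared by cytokines numbered 17 higher for IL-13 and TSLP.

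Leaving out each TGF-beta mouse in turn, the numbers of genes were 27 to 143 higher and 45 to 112 lower for TGF-beta. Between the cytokines the numbers were 25 to 105 higher and 71 to 77 lower in TGF-beta against IL-13, and 28 to 163 higher and 68 to 157 lower in TGF-beta against TSLP. The shared genes numbered 14 to 58 higher and 2 to 23 lower for TGF-beta and IL-13, 12 to 23 higher and 9 to 10 lower for TGF-beta and TSLP, and 10 to 22 higher and 1 to 3 lower for all 3 cytokines. Pearson's r across genes was 0.538 to 0.618 for TGF-beta and IL-13. The numbers of lists were 4 to 10 above the band for TGF-beta and 4 to 5 below the band for TGF-beta. The list medians were -0.51 to 0.035 for skeletal muscle under TGF-beta, -0.18 to 0.36 for endothelial and lymphatic under TGF-beta, and -0.0011 to 0.32 for cell cycle under TGF-beta.

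With one cytokine set against PBS distal and the other against PBS local, r across genes was 0.257 for TGF-beta and IL-13 with IL-13 against PBS distal and 0.411 with TGF-beta against it. For TGF-beta and TSLP it was 0.019 with TSLP against PBS distal and 0.159 with TGF-beta against it, and for IL-13 and TSLP 0.2373 with TSLP and 0.2366 with IL-13 against it.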

Other observations

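The tests chosen only after the result was seen were those of a response common to both TGF-beta mice, of the scaling, of a response to IL-13 or TSLP, of a response to TSLP, of the PBS local array, and of other follicle genes without a filter. The tests of other pancreas genes and of genes at least 4-fold lower in distal skin were set beforehand, although the TSLP values of some of the latter had been seen. Bounds in this section are 95% bootstrap bounds of a list's median, made by resampling its genes within these arrays. Genes of 1 array are not replicates, so the bounds do not measure the spread between mice.

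Erythroid genes were lower in PBS distal skin than at the outlet. The 7 measured members of a list written after Hemgn, Klf1 and Cldn13 had been seen (7 of 15 listed) had a median of -2.27 in PBS distal skin, with 7 of 7 at least 2-fold lower, and without the filter it was -1.88 over 11 genes. Without the 3 genes that prompted the list it was -2.19 over 4. Under the cytokines the medians depended on those choices. They were -1.09 in TGF-beta mouse 1 (-0.68 without the filter, -0.38 without the 3 genes), -0.95 in mouse 2 (-0.39 and -0.31), -0.87 under TSLP (-0.75 and -0.53) and -0.45 under IL-13 (-0.31 and -0.14). Hemgn was at -1.28 in mouse 2 and Slc4a1 at -0.25.

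Hair follicle genes were high in TGF-beta mouse 2, with a list median of 4.81 over 23 genes. All 23 were at or above the filter in mouse 2, but only 3 in mouse 1 and 1 in PBS local skin. The same genes were also higher in arrays without TGF-beta, with medians of 1.32 under IL-13 (16 at least 2-fold higher) and 0.97 in PBS distal skin (11). Under TSLP the median was 0.03, with 0 at least 2-fold higher. Both the idea of a response common to the TGF-beta mice and that of the array scaling were argued against, since mouse 1 had a median of 0.0991 (upper bound 0.534) and quantile normalization left 4.65 between the mice (lower bound 2.82). Genes of the growing follicle and of pigment cells outside that list had a median of 1.22 in mouse 2 over mouse 1 (bounds 0.748 and 1.92). This covers the 14 of 20 listed genes with a named probe set, with no filter, since most of those above the filter passed it in mouse 2 only. The most abundant of them in mouse 2, Krt72, had a signal of 1171 there and 11.9 in PBS local skin, where 2 of the 14, Rab38 and Krt32, passed the filter. A larger share of growing follicles in that piece of skin may account for the pattern, as a hypothesis. Whether TGF-beta or the mouse set that share stays untested.

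Exocrine pancreas genes moved together across the arrays, with medians over 16 genes of 1.61 under IL-13, 1.43 under TSLP, 1.23 in TGF-beta mouse 2, -1.35 in TGF-beta mouse 1 and -2.07 in PBS distal skin. The most abundant under IL-13, Cela1, had a signal of 3225 under IL-13 and 1132 in PBS local skin, where 13 of the 16 passed the filter. The opposite values of the TGF-beta mice argue against a response common to both. RNA from pancreas could be a source, but of the 17 further pancreas genes only Pnliprp2 passed the filter (2.16 in mouse 2 over mouse 1), too few to decide. Without the filter the median was 0.39 over 9 genes near background. A response to IL-13 or TSLP is argued against as the whole cause, since each of the 3 arrays that received neither lay at least 1.23 from PBS local (bounds 1.07 and 1.38 in mouse 2). With 1 array each, a response to IL-13 or TSLP as a part of it in those arrays (medians 1.61 and 1.43) cannot be told apart from their mice. Prss2 was at 1.95 under IL-13 and -1.31 in mouse 1.

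Muscle regeneration genes were lower in the TSLP array, with a median of -0.744 over 8 genes, and 1 array cannot separate a response to TSLP from its mouse. Less tissue of the pump wound in that piece could lower them, and 62 other genes at least 4-fold lower in distal skin had a median of -0.293 under TSLP, with bounds of -0.578 and 0.158 that leave it open. Their shared control also biases that median downward. Exocrine pancreas genes among the 62, such as Cpa1 (1.09 under TSLP) and Ctrb1 (1.47), pull it upward, so it cannot decide. The 62 were chosen by their difference between outlet and distal skin alone, which holds body site as well as the pump, so they do not measure wound tissue as such. An unusually high PBS local array is likewise open, with a median of -0.572 for TSLP minus the mean of the other 3 cytokine arrays and an upper bound of -0.15.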
